A study of Homo sapiens with 12 samples.

How the data were processed

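The deposited table holds 1 intensity value per probe set and array, 22277 probe sets on 12 arrays, made with the Affymetrix software GCOS, per the submitters' processing notes, whose version is not stated. Biotin-labelled cRNA was prepared from total RNA by the standard Affymetrix protocol, per the labels' protocols. How probes were summarised and how background was treated is not given in the sources used here. The values are linear, and the mean between the lowest and highest 2% of each array lies between 499.9 and 501.1, so the arrays share 1 scale as deposited.

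Values were taken as deposited, and log2(value + 12) was used throughout, where 12 is the 20th percentile of all values. The 62 control probe sets were set aside. Of the 22215 others, 19064 carried 1 gene symbol, 1043 several and 2108 none, and 19052 of those with 1 symbol were matched by Entrez ID to the gene table, with 0 symbols changed. Each of the 11963 genes named was represented by its probe set with the highest mean, and the 7178 genes whose mean log2 value reached the 40th percentile (6.61, a signal of 85.8) were tested. BRAF has no probe set that passed these steps and was not analysed here.

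Expression was compared with limma 3.58.1 in R 4.3.3 (moderated test, prior variance with a trend on mean level, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), with cell line as a block. The 250 nM comparison used 10 arrays (4 residual degrees of freedom) and the comparisons with 1000 nM used the 6 arrays of SkMel-19 and Malme3M (2 residual degrees of freedom). In those 6 arrays the error of every comparison is pooled over both lines and both doses. The pairing rests on the cell line in the labels. With each gene's mean per group subtracted, DMSO and 250 nM arrays of the same line correlated at 0.898 to 0.931, and those of different lines at no more than -0.135. When values within lines are high, subtracting the means itself pushes those between lines below 0 on average.

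Gene lists, 27 of them, were fixed before the data were examined, as were the comparisons, the rule for naming genes and the other settings to be tried. The 26 lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera uses only the residual degrees of freedom, 4 or 2 here, and so has little power. The counts adjusted over the list alone use only the p-values of the members. The list test between the doses was added later.

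Genes named at 250 nM are the 12 largest falls and 12 largest rises that passed and moved the same way in all 5 lines, 12 genes named whatever their result, and up to 4 members per list with the largest change among those that passed, or the 2 with the smallest p where none did. At 1000 nM they are the 5 largest falls and 5 largest rises and the same 12 genes, and between the doses, where 0 genes passed, the 5 with the smallest p. FOSL2, ETS1, MAD2L1, CKS2, CDKN2D, CD44 and MMP2, which moved against their list or beside it, the members given for each list at 1000 nM, and DDIT4 and the other stress genes given between the doses were chosen after their values were seen. Signals of named genes were set against 85.8 after the results were seen. Named genes that passed at 250 nM had 79 other probe sets above the filter, of which 2 had the opposite sign. Sizes could differ in either direction: another probe set gave 1.08 for SEMA3C, -2.44 for MAFF and -1.01 for CDC25A, all smaller, and 1.99 for ID2, which is larger.

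The steps were tested on simulated data, 5 runs with 200 changed genes among the 7178. In the 250 nM comparison 55.5% of genes with a log2 change of 0.5 were called, 90.1% at 1 and 100% at 2, and 4.26% of the genes called were unchanged. In the 1000 nM comparison 8.06%, 50.7% and 83.0% were called, with 1.65% of calls unchanged. For 250 nM in the same 2 lines the shares were 7.16%, 51.0% and 82.7% (1.66% unchanged), and between the doses 8.96%, 52.5% and 83.3% (3.37% unchanged). A shifted list was called in 5 of 5 runs and a list without a shift in 0. The noise was drawn independently for each gene, so these runs do not test the list calls where genes are correlated. The genes of the shifted list came on top of the 200. Control ratios were compared by a two-sided exact sign-flip test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.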

Results

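Gene expression was measured on 12 arrays in 5 human melanoma cell lines that carry the V600E form of BRAF, a kinase that passes growth signals through MEK to ERK. The lines were SkMel-1, SkMel-5, SkMel-28, SkMel-19 and Malme3M. Each line was kept for 8 h with the solvent DMSO or with 250 nM PLX4032 (vemurafenib), a small-molecule inhibitor of RAF kinases, and SkMel-19 and Malme3M were also treated at 1000 nM. There was 1 array per line and dose, so the 5 lines were the replicates of the 250 nM comparison and 2 lines those of the comparisons with 1000 nM. The median signal per array lay between 102.5 and 130.4. Of 11963 genes with a named probe set, 7178 were bright enough to be tested.

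The first comparison asked which transcripts changed within 8 h when RAF was inhibited at 250 nM. DUSP6, the phosphatase that inactivates ERK, had the largest fall (log2 fold change -5.04, SE 0.57, n = 5 lines, limma adjusted p = 0.000679). Its signal at 250 nM lay under 85.8, the level of the filter, in 4 of 5 lines, so the size of the fall rests on the pseudocount, and with every signal under 85.8 raised to that level the mean log2 fold change was -4.13. SPRY2 and SPRY4, feedback inhibitors of receptor signalling, fell as well (-3.92, SE 0.32 and -3.29, SE 0.30). CCND1, which encodes cyclin D1 and drives entry into the cell cycle, fell 8.5-fold (-3.09, SE 0.30), and the transcription factor gene MYC fell 5.18-fold (-2.37, SE 0.30, limma adjusted p = 0.000968). The largest rise was that of PNRC1, a nuclear receptor coactivator (2.06, SE 0.21, 4.17-fold, limma adjusted p = 0.000397), and PPARGC1A, the coactivator that promotes mitochondrial biogenesis, rose 3.62-fold (1.86, SE 0.18). Each of these genes moved the same way in all 5 lines.

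Besides DUSP6, SPRY2, SPRY4 and CCND1, the 12 largest falls included the stress-response gene IER3 (-3.51, SE 0.37), FOSL1, a subunit of the AP-1 transcription factor (-3.47, SE 0.28), and MAFF, a small MAF transcription factor (-3.35, SE 0.40). TNFRSF12A, the receptor for the cytokine TWEAK, fell (-2.92, SE 0.12) with the smallest limma adjusted p of all genes tested, 1.03e-05. The potassium channel gene KCNN4 (-2.67, SE 0.19), the Notch target HES1 (-2.65, SE 0.38) and the ETS factor ETV5 (-2.61, SE 0.28) were also among the falls, and 1 of the 12 is not described. Among the 12 largest rises were SEMA3C, a secreted semaphorin (1.94, SE 0.25), and STON1, an endocytic adaptor (1.88, SE 0.24). GALNT3, which starts mucin-type glycosylation, rose (1.79, SE 0.17), as did HPGD, which degrades prostaglandins (1.78, SE 0.20), ID2, an inhibitor of basic helix-loop-helix factors (1.60, SE 0.10, lowest in SkMel-5 at 1.12), and the hyaluronan synthase HAS2 (1.48, SE 0.10). The aspartoacylase gene ASPA (1.55, SE 0.26), the cation channel TRPM1 (1.54, SE 0.21), the ATP-gated channel P2RX7 (1.46, SE 0.18) and PDE4DIP, a Golgi and centrosome anchor (1.40, SE 0.14), completed the rises. Of the 12 largest falls 9 had a 250 nM array under a signal of 85.8, and of the 12 largest rises 8 had a DMSO array under it, so the size and order of these changes also depend on the pseudocount. The same holds for the sizes of FOSL2, KLF9, CDKN2D, KIT, MET, EPHA2, LIF, CXCL1, VEGFA, PMAIP1, SLC2A3, PFKFB2, TFEB, CTSK, PLK3 and MMP2, given below, each with an array under 85.8.

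**Figure D1:**
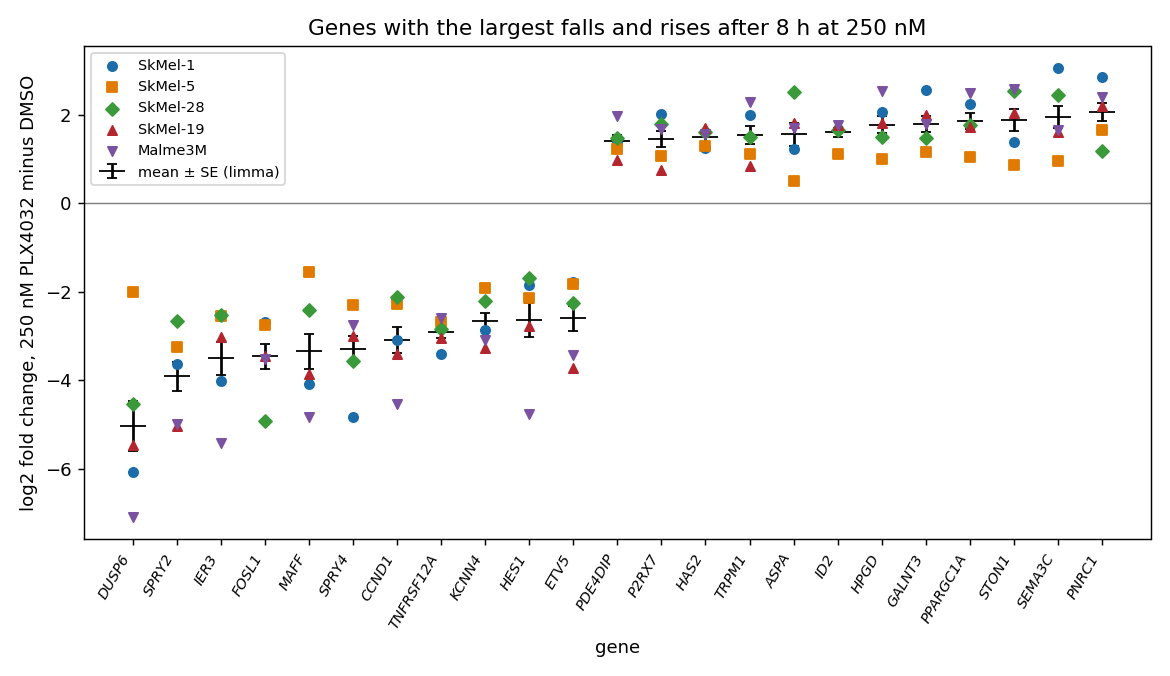
Log2 fold change (250 nM PLX4032 minus DMSO, vertical axis) of 11 of the 12 genes with the largest falls and the 12 with the largest rises, 1 symbol per cell line, with the limma mean and its SE in black. All 5 lines lie on the same side of 0 for every gene shown, as the choice of genes required. IER3, above a signal of 85.8 on every array, stood at -5.42 in Malme3M and -2.56 in SkMel-5.

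In all, 2029 of the 7178 genes changed at a limma adjusted p (Benjamini-Hochberg) under 0.05, with cell line as a block, 1088 of them higher (53.6%) and 941 lower. With each array centred on its median, 876 of 1944 genes were higher (45.1%), and without SkMel-19 or Malme3M 49.5% and 48.8% were, so neither direction held a stable majority. The large changes were mostly falls: 117 genes fell and 52 rose by at least 2-fold, and 24 fell and 1 rose by at least 4-fold. Of the 2029 genes, 1850 moved the same way in all 5 lines, against 2694 of all 7178 genes tested. The count was 1288 without SkMel-19 and 1339 without Malme3M, when 4 lines remained.

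ERK feedback regulators fell together: 8 of 10 measured members fell over all genes tested and 8 when adjusted over the list alone, with a median log2 fold change of -1.76. Besides DUSP6, SPRY2 and SPRY4, the ERK phosphatase DUSP4 fell (-2.29, SE 0.23). The shift of the list passed the test (limma's camera adjusted p = 9.52e-08, adjusted p = 0.0959 with an estimated correlation). All 9 measured genes of a MAPK pathway activity score fell, and all 9 adjusted over the list alone, among them the ETS factor ETV4 (-1.97, SE 0.18) and PHLDA1 (-0.97, SE 0.18), with a median of -2.61 (limma's camera adjusted p = 7.41e-10, adjusted p = 0.0959 with an estimated correlation). Members of both lists were known from earlier work as outputs of ERK signalling, so their direction is not independent evidence.

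Immediate early and AP-1 or ETS transcription factor genes also fell as a group. Of 24 measured, 17 fell and 2 rose over all genes tested, and 19 and 2 did so adjusted over the list alone, with a median of -1.10 (limma's camera adjusted p = 2.81e-09, adjusted p = 0.124 with an estimated correlation). IER3, FOSL1 and MAFF were among the falls, whereas FOSL2 (0.98, SE 0.26) and ETS1 (0.56, SE 0.14) rose. EGR1 lay below the signal filter, and in the fit without that filter its log2 fold change was -2.58 (SE 0.40, limma adjusted p = 0.00506). The genes that encode the RAS-RAF-MEK-ERK components themselves did not shift as a list (limma's camera adjusted p = 0.543). Of 16 measured, 2 fell, also adjusted over the list alone: the kinases MAPKAPK2 (-0.44, SE 0.11) and RPS6KA3 (-0.36, SE 0.09). Neither is itself a RAF, MEK or ERK kinase. BRAF itself was not analysed here.

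Genes of the G1/S and the G2/M phase moved apart. Of 36 measured G1/S and DNA replication genes, 18 fell and none rose (19 fell adjusted over the list alone), with a median of -0.24 (limma's camera adjusted p = 3.97e-07, adjusted p = 0.243 with an estimated correlation). After CCND1 the largest falls were in the phosphatase CDC25A (-1.64, SE 0.12), the replication licensing factor CDC6 (-1.01, SE 0.12) and the cyclin CCNE2 (-0.99, SE 0.19). Of 36 measured G2/M and mitosis genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.14 (limma's camera adjusted p = 0.00533, adjusted p = 0.351 with an estimated correlation). KIF20A, a kinesin of cytokinesis (0.74, SE 0.09), CDC25C, which activates CDK1 (0.61, SE 0.11), the spindle protein HMMR (0.49, SE 0.07) and the kinetochore gene CENPF (0.46, SE 0.11) rose. The spindle checkpoint gene MAD2L1 (-0.30, SE 0.08) and CKS2 (-0.29, SE 0.06) fell. Among 20 cell cycle inhibitors and quiescence genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone), but the list did not pass (limma's camera adjusted p = 0.0884). The atypical cyclin CCNG2 (1.31, SE 0.13), the transcriptional coregulator CITED2 (1.13, SE 0.17) and TXNIP, which restrains glucose uptake (0.99, SE 0.20), rose, whereas the Kruppel-like factor KLF9 (-1.31, SE 0.30) and the CDK inhibitor CDKN2D (-0.68, SE 0.16) fell.

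**Figure D2:**
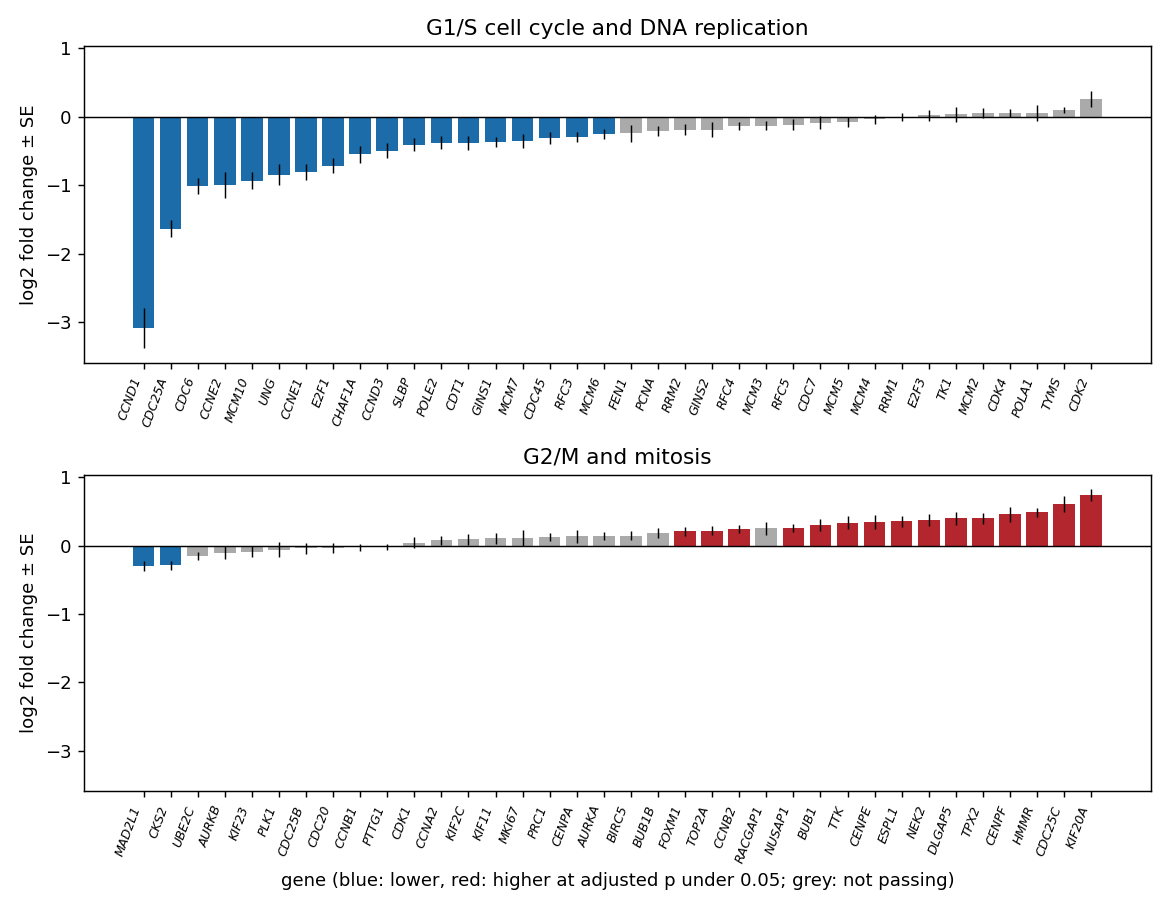
Log2 fold change with SE (limma, 5 lines, 250 nM PLX4032 minus DMSO) of each measured gene of the G1/S list and the G2/M list, with genes past an adjusted p of 0.05 in colour. In the G1/S list 18 genes are lower and none higher, and in the G2/M list 15 are higher and 2 lower.

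Melanocyte lineage and pigmentation genes rose as a list, with 10 of 23 measured members higher and 1 lower (12 and 1 adjusted over the list alone) and a median of 0.27 (limma's camera adjusted p = 0.00100, adjusted p = 0.0959 with an estimated correlation). TRPM1, the receptor tyrosine kinase KIT (1.29, SE 0.22) and RAB27A, which moves melanosomes (0.86, SE 0.08), rose. MC1R, the melanocortin receptor that stimulates pigment synthesis, fell 4.29-fold (-2.10, SE 0.23, limma adjusted p = 0.000542), in all 5 lines. MITF, the master transcription factor of the lineage, did not pass (0.11, SE 0.07, limma adjusted p = 0.247) and was higher in 4 of 5 lines.

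Receptor tyrosine kinases split: of 13 measured, KIT and MET (0.94, SE 0.17) rose and EPHA2 (-1.74, SE 0.20) and EPHB4 (-0.54, SE 0.12) fell, with the same 2 and 2 adjusted over the list alone and no shift of the list (limma's camera adjusted p = 0.947). The other probe set of EPHB4 stood at only -0.08, and those of MET at 0.63, 0.68 and 0.40. Secreted growth factors and cytokines fell in 4 of 6 cases (5 adjusted over the list alone), with a median of -1.32 (limma's camera adjusted p = 0.000806, adjusted p = 0.243 with an estimated correlation). They were LIF (-2.58, SE 0.36), the stress-induced GDF15 (-2.32, SE 0.41), the chemokine CXCL1 (-1.65, SE 0.19) and the angiogenic factor VEGFA (-0.98, SE 0.24). The other probe sets of VEGFA above the filter fell less (-0.45 and -0.50). With signals under 85.8 raised to that level the mean was -1.80 for LIF and -1.16 for CXCL1. In the BCL2 family, which governs apoptosis, 4 of 14 measured genes fell and 1 rose (4 and 2 adjusted over the list alone), with no shift of the list (limma's camera adjusted p = 0.247). The falls included the proapoptotic PMAIP1 (-1.41, SE 0.24) and BID (-0.56, SE 0.13) and the antiapoptotic MCL1 (-0.53, SE 0.06), and the mitophagy receptor BNIP3L rose (0.51, SE 0.08).

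Genes for ribosome production fell broadly. Of 32 measured nucleolus and ribosome biogenesis genes, 28 fell and none rose, and the same number fell adjusted over the list alone, with a median of -0.76 (limma's camera adjusted p = 7.12e-18, adjusted p = 0.0959 with an estimated correlation). POLR1G, a subunit of RNA polymerase I (-1.53, SE 0.18), and the ribosome assembly factors BRIX1 (-1.45, SE 0.11), BYSL (-1.34, SE 0.14) and RRS1 (-1.28, SE 0.15) fell most. Purine and pyrimidine synthesis genes fell in 9 of 19 cases and rose in none (11 fell adjusted over the list alone), with a median of -0.21 (limma's camera adjusted p = 2.12e-05, adjusted p = 0.0959 with an estimated correlation). PPAT, the first committed enzyme of purine synthesis (-0.96, SE 0.10), the CTP synthase CTPS1 (-0.91, SE 0.13), UMPS (-0.57, SE 0.09) and GART (-0.54, SE 0.07) were among them.

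Of 22 measured glycolysis and glucose uptake genes, 4 fell and 2 rose, also adjusted over the list alone, and the list did not shift (limma's camera adjusted p = 0.543). The glucose transporter SLC2A3 (-2.13, SE 0.37), the hexokinase HK2 (-1.54, SE 0.21) and PFKFB3 (-0.67, SE 0.17) fell, and PFKFB2 rose (0.59, SE 0.14). Oxidative phosphorylation genes and their regulators rose slightly, 11 of 33 higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 0.13 (limma's camera adjusted p = 0.00130, adjusted p = 0.351 with an estimated correlation). Besides PPARGC1A, the respiratory chain genes NDUFB5 (0.35, SE 0.08) and SDHD (0.33, SE 0.10) rose, and TFAM, which maintains mitochondrial DNA, fell (-0.52, SE 0.08). Of 14 cholesterol synthesis and uptake genes, 3 fell, also adjusted over the list alone (limma's camera adjusted p = 0.0332, adjusted p = 0.351 with an estimated correlation): the sterol enzymes MSMO1 (-0.85, SE 0.15, with Malme3M at -1.66), SQLE (-0.67, SE 0.16) and IDI1 (-0.37, SE 0.11). Lysosome genes rose, 14 of 28 with none lower (17 adjusted over the list alone) and a median of 0.26 (limma's camera adjusted p = 1.85e-05, adjusted p = 0.243 with an estimated correlation). TFEB, the transcription factor that controls lysosome genes (1.26, SE 0.21), the lysosomal calcium channel MCOLN1 (0.60, SE 0.19), GM2A (0.55, SE 0.09) and the protease CTSK (0.51, SE 0.17) rose most.

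**Figure D3:**
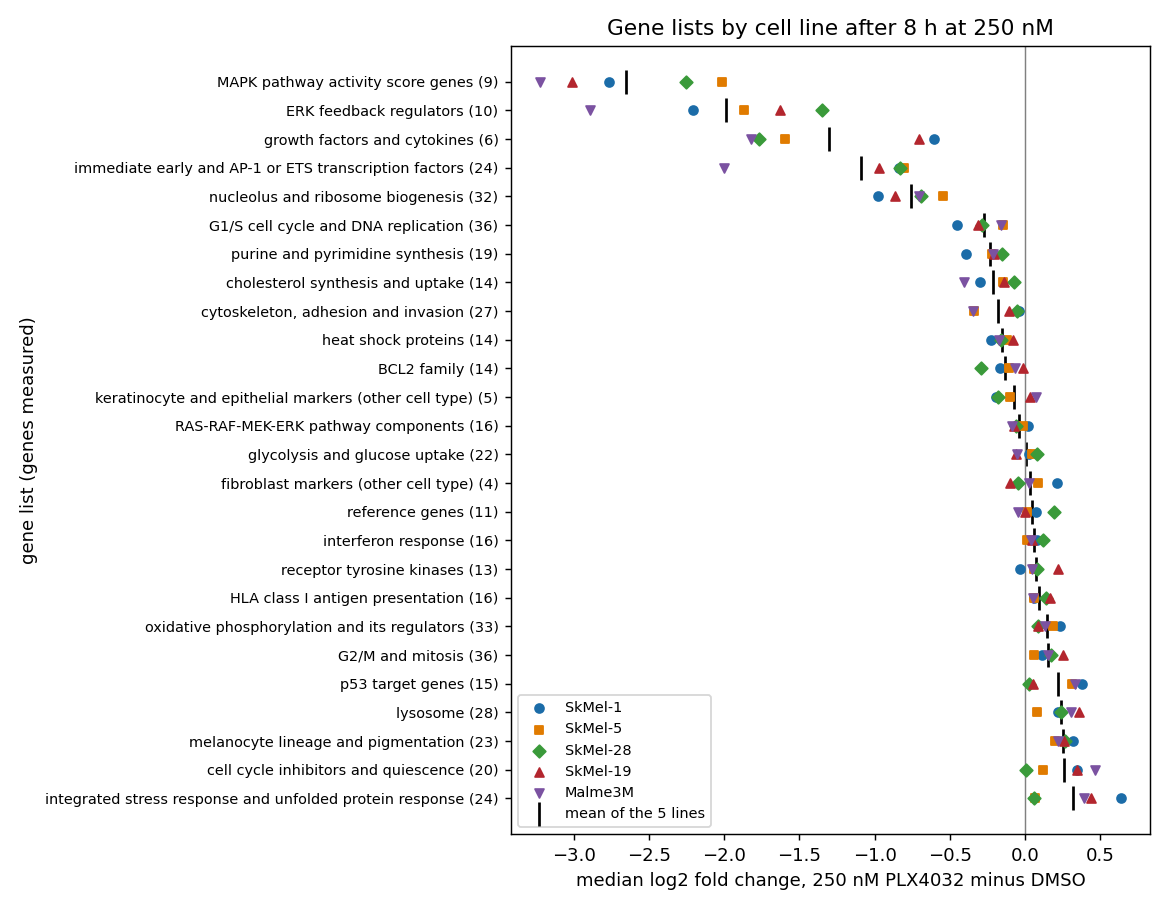
Median log2 fold change (250 nM PLX4032 minus DMSO, horizontal axis) of the measured genes of each fixed list in each of the 5 cell lines, with the mean of the lines as a black bar and the number of genes measured in brackets. Medians of the nucleolus list lay between -0.98 in SkMel-1 and -0.55 in SkMel-5, and those of the lysosome and G2/M lists lay above 0 in every line.

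Stress programmes were mixed. In the list of integrated stress response and unfolded protein response genes, 9 of 24 rose and 3 fell (11 and 3 adjusted over the list alone), and the list did not pass (limma's camera adjusted p = 0.138). The amino acid synthesis genes ASNS (0.90, SE 0.28), PSAT1 (0.83, SE 0.18, with SkMel-1 at 1.86) and PSPH (0.71, SE 0.13) rose, as did DDIT3, which encodes the stress transcription factor CHOP (0.85, SE 0.18). Of 15 p53 targets 6 rose and 2 fell (7 and 4 adjusted over the list alone), with no shift of the list (limma's camera adjusted p = 0.327). SESN1 (0.72, SE 0.11), the DNA repair gene DDB2 (0.45, SE 0.12) and CCNG1 (0.44, SE 0.08) rose, and the kinase PLK3 fell (-1.26, SE 0.15). Of 16 interferon response genes, the transcription factors IRF9 (0.74, SE 0.08) and IRF7 (0.45, SE 0.11) rose and USP18 fell (-0.46, SE 0.12), with the same 2 and 1 adjusted over the list alone and no shift of the list (limma's camera adjusted p = 0.586). Genes of HLA class I antigen presentation passed as a list (limma's camera adjusted p = 0.0351, adjusted p = 0.265 with an estimated correlation) with 2 of 16 members higher, HLA-G (0.25, SE 0.08) and the chaperone CANX (0.14, SE 0.04), and 0 adjusted over the list alone. The list kept its call in only 7 of 13 alternative settings. All 4 probe sets of HLA-G, the one reported included, are of a kind that can bind related transcripts (_x_at), and 2 of the others had the opposite sign (-0.01 and -0.16), so the value for HLA-G may not be that of HLA-G alone.

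Heat shock protein genes fell as a list (limma's camera adjusted p = 0.0199, adjusted p = 0.193 with an estimated correlation), with 4 of 14 lower and 2 higher (6 and 2 adjusted over the list alone). The cochaperones CHORDC1 (-0.50, SE 0.09) and DNAJA1 (-0.46, SE 0.08) fell, and DNAJB4 (0.75, SE 0.12) and HSPB1 (0.41, SE 0.09) rose. Of 27 cytoskeleton, adhesion and invasion genes, 9 fell and 2 rose, also adjusted over the list alone (limma's camera adjusted p = 0.0159, adjusted p = 0.351 with an estimated correlation). PLAUR, the receptor of urokinase (-1.48, SE 0.20), the metalloproteinase inhibitor TIMP3 (-1.48, SE 0.15, with SkMel-28 at -0.63), the adhesion scaffold NEDD9 (-0.98, SE 0.22) and the actin crosslinker ACTN1 (-0.77, SE 0.12) fell most, whereas the adhesion receptor CD44 (0.27, SE 0.07) and the gelatinase MMP2 (0.57, SE 0.11) rose. The other probe sets of TIMP3 fell less (-0.80, -0.79 and -0.80), and those of PLAUR stood at -1.64 and -0.22, so these sizes depend on the probe set.

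Markers of other cell types were mostly below the signal filter. Of 16 fibroblast markers 4 were measured and none passed limma, also adjusted over the list alone (limma's camera adjusted p = 0.947): LUM had a log2 fold change of 0.18 (limma adjusted p = 0.133) and TWIST1 of -0.09 (limma adjusted p = 0.614). The single blood cell marker measured, LCP1, had a log2 fold change of 0.23 (limma adjusted p = 0.190). Of 5 keratinocyte and epithelial markers the keratin gene KRT18 fell (-0.77, SE 0.15), also adjusted over the list alone, and the list did not shift (limma's camera adjusted p = 0.543). Of 11 reference genes SDHA rose (0.33, SE 0.07) and HPRT1 fell (-0.25, SE 0.07), again 1 and 1 adjusted over the list alone (limma's camera adjusted p = 0.543). The median log2 fold change of all genes tested was 0.03. In the pathway component, receptor tyrosine kinase and fibroblast lists the median, the mean and the test statistic differed in sign. The ratio of 3' to 5' control signal, a measure of RNA integrity, differed between 250 nM and DMSO by -0.01 on the log2 scale for GAPDH (SD 0.07, n = 5, exact sign-flip p = 0.875) and by -0.02 for ACTB (SD 0.08, n = 5, exact sign-flip p = 0.625), and 5 pairs allow no p below 0.0625.

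The second comparison asked what the higher dose did in SkMel-19 and Malme3M. At 1000 nM the largest falls were in DUSP6 (-6.27, SE 0.47, n = 2 lines, limma adjusted p = 0.00266) and SPRY2 (-5.13, SE 0.31), whose signal at that dose lay under 85.8 in both lines, followed by IER3 (-4.43, SE 0.61), MAFF (-4.43, SE 0.28) and CCND1 (-3.87, SE 0.31). The largest rises were in PNRC1 (2.35, SE 0.11), STON1 (2.25, SE 0.17), PPARGC1A (2.11, SE 0.21), CHAC1, which degrades glutathione and is induced by stress signalling (2.09, SE 0.31), and HPGD (2.05, SE 0.24). SPRY4 (-3.38), ETV4 (-2.10), ETV5 (-3.63), FOSL1 (-3.36) and MYC (-2.70) fell as well. SPRY4 and FOSL1 also lay under 85.8 in both lines at 1000 nM and MAFF in 1, and STON1, CHAC1 and HPGD did in 1 of the DMSO arrays. The sizes of these changes, and the order of the falls and rises, rest on the pseudocount too. PHLDA1 (-1.19, SE 0.37, limma adjusted p = 0.0882) and MITF (0.12, SE 0.08, limma adjusted p = 0.312) did not pass, nor did EGR1 in the fit without the filter (-1.52, SE 0.36, limma adjusted p = 0.0864).

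ERK outputs and the growth programme again fell as groups at 1000 nM. ERK feedback regulators fell in 7 of 10 cases (8 lower and 1 higher adjusted over the list alone; limma's camera adjusted p = 1.80e-06, adjusted p = 0.369 with an estimated correlation), and 8 of 9 activity score genes fell (9 adjusted over the list alone; limma's camera adjusted p = 4.34e-10, adjusted p = 0.375 with an estimated correlation). Of 24 immediate early genes 14 fell, with ETS1 (0.85) higher (16 and 2 adjusted over the list alone; limma's camera adjusted p = 4.34e-10, adjusted p = 0.369 with an estimated correlation). Of 32 nucleolus genes 21 fell, BRIX1 (-1.45) among them (27 adjusted over the list alone; limma's camera adjusted p = 1.10e-16, adjusted p = 0.259 with an estimated correlation), and of 19 nucleotide synthesis genes 4 fell, PPAT (-1.11) among them (8 lower and 1 higher adjusted over the list alone; limma's camera adjusted p = 0.00123, adjusted p = 0.375 with an estimated correlation). G1/S genes fell in 9 of 36 cases, with CDC25A at -1.65 (17 adjusted over the list alone; limma's camera adjusted p = 1.03e-06, adjusted p = 0.377 with an estimated correlation). Growth factors fell in 2 of 6 cases, CXCL1 (-2.17) and GDF15 (-2.41) (3 adjusted over the list alone; limma's camera adjusted p = 0.00364, adjusted p = 0.490 with an estimated correlation). Cholesterol genes fell in 2 of 14 cases, SQLE (-1.21) and IDI1 (-0.68) (4 adjusted over the list alone; limma's camera adjusted p = 0.0339, adjusted p = 0.490 with an estimated correlation). Of 27 cytoskeleton genes 5 fell and 2 rose, with NEDD9 at -1.80 (6 and 2 adjusted over the list alone; limma's camera adjusted p = 0.00598, adjusted p = 0.496 with an estimated correlation).

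Mitotic, lysosomal, pigmentation and stress genes rose as groups at 1000 nM. G2/M genes rose in 8 of 36 cases, with KIF20A at 0.97 (12 adjusted over the list alone; limma's camera adjusted p = 0.000793, adjusted p = 0.389 with an estimated correlation). Cell cycle inhibitors rose in 9 of 20 cases, with CCNG2 at 1.52 and KLF9 lower at -2.11 (11 and 2 adjusted over the list alone; limma's camera adjusted p = 0.025, adjusted p = 0.389 with an estimated correlation). Melanocyte genes rose in 7 of 23 cases, KIT (1.66) among them, with MC1R lower at -2.64 (13 and 1 adjusted over the list alone; limma's camera adjusted p = 0.000897, adjusted p = 0.369 with an estimated correlation). Lysosome genes rose in 10 of 28 cases, with TFEB at 1.74 (16 adjusted over the list alone; limma's camera adjusted p = 2.25e-06, adjusted p = 0.377 with an estimated correlation). The stress response list rose in 10 of 24 cases, with ASNS at 1.82 and DDIT3 at 1.34 (13 higher and 1 lower adjusted over the list alone; limma's camera adjusted p = 0.00364, adjusted p = 0.496 with an estimated correlation). Oxidative phosphorylation genes shifted up (limma's camera adjusted p = 0.0154, adjusted p = 0.375 with an estimated correlation) with PPARGC1A and NDUFB5 (0.38) higher and TFAM (-0.53) lower, also adjusted over the list alone. HLA class I genes shifted up (limma's camera adjusted p = 0.0113, adjusted p = 0.389 with an estimated correlation) with no member past limma, also adjusted over the list alone.

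The other 10 lists did not pass at 1000 nM. Among them, heat shock genes had limma's camera adjusted p = 0.0591, with DNAJB4 (1.10) higher and DNAJA1 (-0.48) lower, glycolysis genes limma's camera adjusted p = 0.312, with HK2 (-2.15) lower, and p53 targets limma's camera adjusted p = 0.332, with SESN1 (0.83) higher. The BCL2 family had limma's camera adjusted p = 0.272, with MCL1 (-0.62) and BCL2L1 (-0.46) lower and BNIP3L (0.58) higher, and receptor tyrosine kinases had limma's camera adjusted p = 0.736, with KIT and MET (1.04) higher and EPHA2 (-1.66) lower. The median, the mean and the test statistic differed in sign in the receptor kinase, glycolysis and keratinocyte lists. Pathway components (limma's camera adjusted p = 0.312), interferon response genes (limma's camera adjusted p = 0.693, with USP18 lower at -0.84), keratinocyte markers (limma's camera adjusted p = 0.766, with KRT18 lower at -1.15), reference genes (limma's camera adjusted p = 0.844) and fibroblast markers (limma's camera adjusted p = 1.00) did not shift. Adjusted over the list alone, USP18 did not pass and KRT18 did, and the counts higher and lower were 1 and 1 for heat shock, 0 and 1 for glycolysis, 1 and 1 for p53, 2 and 3 for BCL2 and 2 and 1 for receptor kinase genes. In total 16 of the 26 lists tested passed camera at 1000 nM and 15 at 250 nM. With an estimated correlation 0 passed at either dose, where the lowest adjusted p was 0.259 at 1000 nM and 0.0959 at 250 nM.

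At 1000 nM 803 genes changed in limma, and in the same fit 814 genes changed at 250 nM in these 2 lines. The error was pooled over both doses. The 250 and 1000 nM arrays of a line correlated at 0.990, those of DMSO and 250 nM at 0.982 in SkMel-19 and 0.976 in Malme3M. The fit counts both treated arrays as separate, so the SE and adjusted p against DMSO may be too small. IER3 at 1000 nM stood at -3.08 in SkMel-19 and -5.78 in Malme3M, with an SE of 0.61. Which direction held more genes turned in other fits at both doses. The fit left 2 residual degrees of freedom, and its counts hung on single arrays: the 1000 nM count was 32 without the SkMel-19 array at that dose, 0 without that of Malme3M and 1541 without the DMSO array of SkMel-19. The 250 nM count in these lines was 72 without the treated array of SkMel-19, 93 without that of Malme3M and 1483 without the DMSO array of SkMel-19.

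The effects at 1000 nM in SkMel-19 and Malme3M were set against those at 250 nM in the other 3 lines, which share no array with them. Across 7178 genes, which are not independent replicates, Pearson's r was 0.830 and Spearman's coefficient 0.757, and the slope of the 1000 nM on the 250 nM effects was 1.07. Of the 803 genes that changed at 1000 nM, 791 (98.5%) had the same sign in the other 3 lines at 250 nM, against 79.6% of all genes tested.

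**Figure D4:**
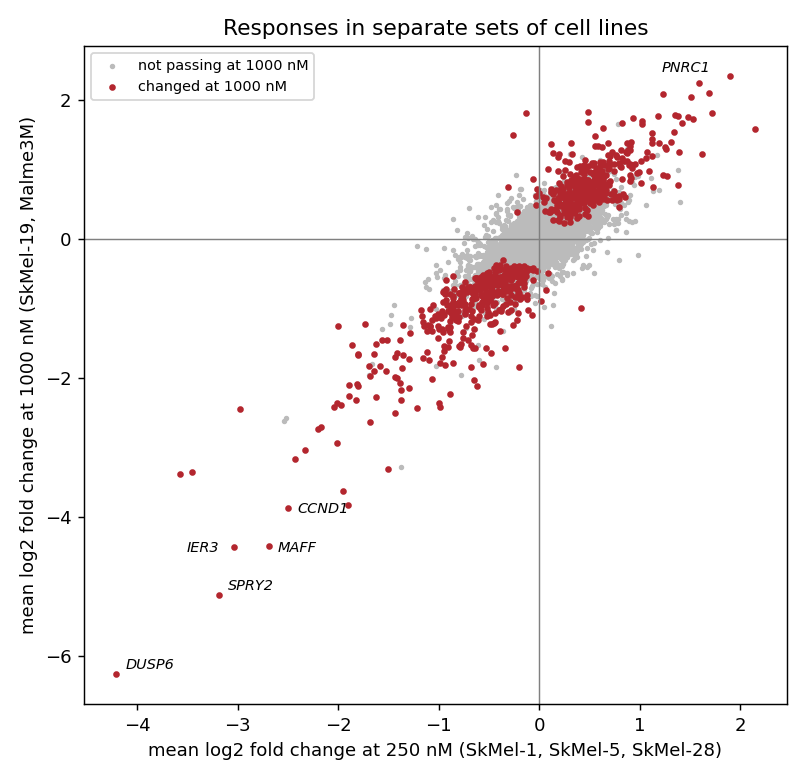
Mean log2 fold change at 1000 nM in SkMel-19 and Malme3M (vertical axis) against that at 250 nM in SkMel-1, SkMel-5 and SkMel-28 (horizontal axis), 1 point per gene, with genes that changed at 1000 nM in colour. Pearson's r across genes was 0.830.

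The third comparison set 1000 nM against 250 nM within SkMel-19 and Malme3M. For CCND1 the difference was 0.10 (95% interval -0.66 to 0.87). The signals of DUSP6, SPRY2 and SPRY4 lay under 85.8 in both lines at 250 nM already, so a further fall could hardly show in their differences of 0.02 (95% interval -1.14 to 1.17), -0.12 (-0.86 to 0.63) and -0.50 (-1.07 to 0.08). In limma 0 genes passed, the smallest adjusted p being 0.999, and 75 genes had an unadjusted p under 0.05. The 5 genes with the smallest p were EEF2KMT, a lysine methyltransferase (1.04, SE 0.22), the acetyltransferase KAT2A (-0.61, SE 0.14), the purine enzyme PFAS (0.45, SE 0.11), the antiapoptotic BCL2L1 (-0.45, SE 0.11) and FPGS, which retains folates in cells (0.89, SE 0.21), each with a limma adjusted p of 0.999. The 95% interval of a difference had a median half-width of 0.33, the same as for each dose against DMSO. The fit of 6 arrays uses a shared error, which includes how the lines differ in their response to the drug. The 75 genes with an unadjusted p under 0.05 were fewer than chance alone would give among 7178. The intervals may therefore be too wide for the dose difference, and 0 genes does not show that the doses acted alike. The number of arrays limits the precision as well.

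A list test between the doses, run after the data were examined, found 1 list past the threshold. Integrated stress response and unfolded protein response genes were shifted up at 1000 nM, with a median difference of 0.15 (limma's camera adjusted p = 0.000361, adjusted p = 0.760 with an estimated correlation), and none of 24 members passed limma on its own, also adjusted over the list alone. The list did not pass fry (fry adjusted p = 0.995), and its estimated correlation was 0.313, above the preset 0.01. The lines went apart: the median difference was 0.38 in Malme3M, where 23 of 24 members were above 0, and -0.10 in SkMel-19, where 6 were. In Malme3M the differences reached 1.13 for CHAC1, 1.12 for DDIT3 and 1.10 for DDIT4, an inhibitor of mTOR signalling, against -0.24, 0.01 and 0.00 in SkMel-19.

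**Figure D5:**
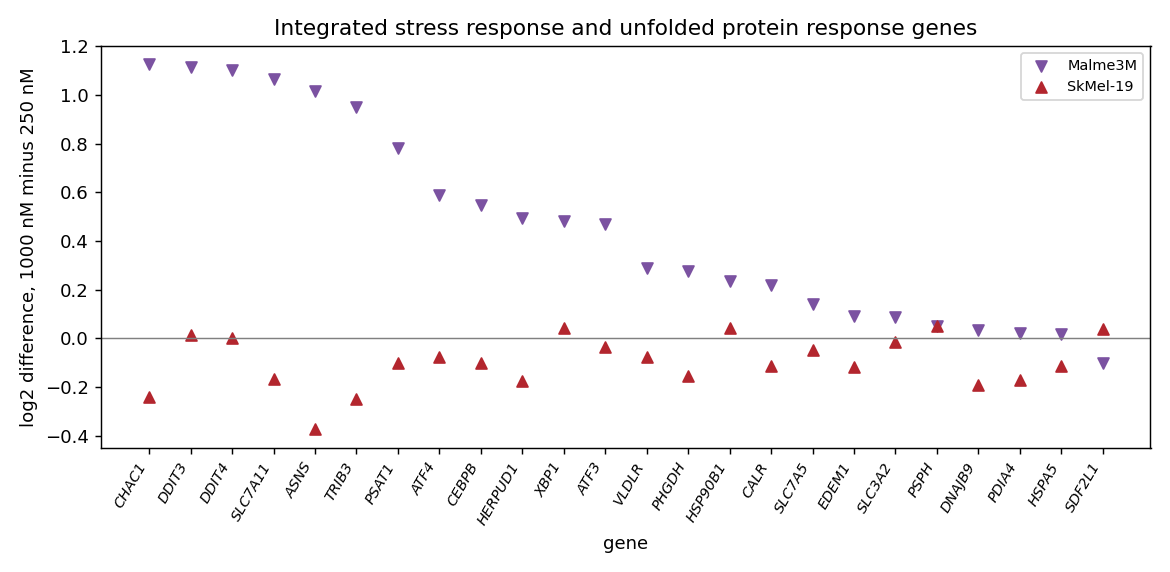
Log2 difference between 1000 nM and 250 nM PLX4032 of the 24 measured stress response genes, in Malme3M and in SkMel-19, 1 array per dose and line, so no error can be drawn. In Malme3M 23 of the 24 genes lie above 0 and in SkMel-19 6 do.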

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

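The results of the next paragraph stood apart from their group by the distance to the nearest other value or by opposite signs in SkMel-19 and Malme3M. The 3 gene patterns further down were picked on reading the results, and the fall expected of TUBB3, the test for a dose effect shared by both lines, the list test between the doses and its stress gene pattern were chosen after the result was seen.

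ID2, an inhibitor of differentiation factors, rose less in SkMel-5 (1.12) than in the other 4 lines (1.66 to 1.77) at 250 nM. The sterol enzyme gene MSMO1 stood at -1.66 in Malme3M against -0.77 to -0.54 elsewhere. PSAT1, a serine synthesis enzyme, stood at 1.86 in SkMel-1 against 0.49 to 0.63 elsewhere, and the protease inhibitor TIMP3 at -0.63 in SkMel-28 against -1.77 to -1.54. Of 105 genes looked at in this way 4 stood apart, and chance gives about 1 in 20 groups. Among 14 groups of array measures 2 did: the highest signal of the SkMel-28 DMSO array was 15576.8 (16410 to 16654 on the other DMSO arrays), and 14.9% of the values of the SkMel-28 array at 250 nM lay below the pseudocount (20.2% to 21.5% on the others). On the SkMel-28 DMSO array that share was 16.6%, the lowest of the DMSO arrays. Of 106 genes compared between SkMel-19 and Malme3M over both doses, 2 had opposite signs: TWIST1 (0.32 and -0.31, a difference of 0.63) and LCP1 (0.34 and -0.16, a difference of 0.50), and neither difference was tested.

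The count of 2029 genes changed at 250 nM was set against other splits of the 10 arrays into 5 and 5 with line as a block. In 100 splits drawn, the real one included, 1 gave as many genes, the real one, and the highest other gave 3. Of these splits 86 part only 1 or 3 of the 5 pairs of arrays of 1 line, while the real one parts all, so in those 86 the treatment adds to the residual and few genes are expected. The splits that part all 5 pairs number 16, too few for a share under 0.05: 1 gave as many genes, the real one, and the highest other gave 1. In the others of the 16 the treatment lies on opposite sides in different lines. It thus adds to the residual there too, and few genes are expected. Neither set of splits shows what chance alone would give.

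G2/M genes such as KIF20A and CDC25C were higher at 250 nM while G1/S genes such as CDC25A and CDC6 were lower. Array scaling is argued against by the G2/M median relative to all genes, 0.11 under quantile normalization (SE over lines 0.03) and 0.11 with the values as deposited. The signal level of the genes is argued against by random lists matched on mean signal, of which 0.42% had a median as high. With an estimated inter-gene correlation neither list passed (limma's camera adjusted p = 0.351 for G2/M and 0.243 for G1/S), in a test with only 4 residual degrees of freedom. No cell cycle phase was measured, so no explanation is put forward.

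MC1R fell while KIT, TRPM1 and RAB27A rose. Transcripts that read through from MC1R into its neighbour TUBB3 could tie both signals. TUBB3 had a log2 fold change of -0.20 (SE 0.11) against -2.10 for MC1R, and its other probe set one of -0.32 (SE 0.17). This decides nothing, because TUBB3 is so bright that losing the signal MC1R lost would lower its probe sets by only -0.31 and -0.48, each within 2 SE. Array scaling moved the value for MC1R little (-2.09 under quantile normalization, -2.13 with median centring).

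Stress response genes such as CHAC1, DDIT3 and DDIT4 were higher at 1000 nM than at 250 nM in Malme3M. Array scaling is argued against by a Malme3M median relative to all genes of 0.40 under quantile normalization (0.39 as deposited), and the signal level of the genes by matched random lists, of which 0.01% were as high, the smallest share that 10000 lists can give. In SkMel-19 the median was -0.10, and 0.05% of matched random lists were as low, which describes these arrays and not other cultures. With 1 array per line and dose the difference between doses has no replicate spread in either line, so a dose effect shared by both lines and a difference between cultures cannot be told apart.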

How the results depend on the processing

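Of the values below, leaving out single arrays for the lists at 1000 nM was chosen after the result was seen. Without the pairing by cell line as a block, the count at 250 nM was 13 in place of 2029, that at 1000 nM 0 in place of 803 and that at 250 nM in the same 2 lines 0 in place of 814. Without the filter on low values the last counts were 445 and 430, and without a trend of the prior variance the 1000 nM count was 530; the cause was not tested. In 1 fit over all 12 arrays the 250 nM effect is that of all 5 lines by construction, with 2277 genes. Leaving out 1 line gave 1288 (SkMel-19, replicate 4) to 1836 genes at 250 nM, and 1339 without Malme3M (replicate 5), with 4 lines left. Leaving out 1 array gave 0 to 1541 genes at 1000 nM: 1541 without the DMSO array of SkMel-19, 32 without its 1000 nM array and 0 without that of Malme3M. For 250 nM in these lines it gave 72 to 1483: 1483 without the DMSO array of SkMel-19, 72 without its 250 nM array and 93 without that of Malme3M. A lone array left in a group was assumed to vary like the others. Other settings kept the 250 nM count between 1462 and 2277, and quantile normalization and median centring kept 1938 of 2026 and 1817 of 2029 genes. The share of higher genes at 250 nM was 53.6% as deposited, 45.1% with median centring, 49.5% without SkMel-19 and 48.8% without Malme3M, so the majority turned. Between the doses limma gave 0 genes in all 15 alternatives, with 75 at an unadjusted p under 0.05 in the fit reported.

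With an estimated inter-gene correlation 0 lists passed at 250 nM and 0 at 1000 nM, against 15 and 16 with the preset one. With fry 15 and 13 passed. With an estimated correlation camera uses only the residual degrees of freedom, 4 at 250 nM and 2 at 1000 nM. A list can thus lose its call there without any added correlation. How much each of the 2 contributed was not tested. Lists with an estimated correlation under the preset 0.01 lost their call too, which argues against a higher correlation as the cause in them. They were the melanocyte and heat shock lists at 250 nM and the melanocyte, nucleolus, oxidative phosphorylation and ERK feedback lists at 1000 nM. For the nucleolus list at 1000 nM the estimate was -0.0165, and limma's camera p went from 4.22e-18 to 0.00996. The lists that passed fry were not all the same ones. At 250 nM the cholesterol (fry adjusted p = 0.0747) and cytoskeleton (0.0544) lists did not pass fry. The cell cycle inhibitor (fry adjusted p = 0.0114) and interferon (0.0116) lists did. At 1000 nM the stress response (fry adjusted p = 0.187), growth factor (0.196), cholesterol (0.202) and cytoskeleton (0.154) lists did not pass fry. The receptor tyrosine kinase list (fry adjusted p = 0.0398) did. At 250 nM the HLA list passed in 7 of 13 other alternatives (fry and the fit without the block not counted), the cholesterol list in 10 and the cytoskeleton list in 12, and the other 12 lists passed in all of theirs. At 1000 nM the cholesterol list passed in 9 of 12, the HLA and cytoskeleton lists in 10, the stress response and oxidative phosphorylation lists in 11, and the other 11 in all of theirs. Each list kept its direction, and leaving out 1 array gave 13 to 17 lists at 1000 nM. The correlation between separate lines (0.830) was 0.630 with no filter, 0.849 with the filter at the 60th percentile, 0.757 as Spearman's coefficient and 0.761 to 0.803 without 1 line; the cause was not tested. Named genes at 250 nM gave 1635 values under the alternatives, of which 1468 stayed on their side of the threshold, 167 no longer passed (92 of them without the block) and 0 reversed. Of 101 genes called, 84 passed in all alternatives with the block in which they were tested. At 1000 nM 36 of 248 values no longer passed and 2 newly passed. None of the 15 genes called there passed in all alternatives with the block. Of 32 counts within lists, 12 moved beyond 1.5 times with the filter at the 60th percentile, 3 to 9 without 1 line and 32 without the block.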

Other observations

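Gene families formed by symbol, the slopes of single lines and their tests were chosen after the data were examined. Among 96 families with at least 8 tested members outside the fixed lists, 3 shifted at 250 nM in limma's camera, and 0 did with an estimated correlation (adjusted p = 0.826 for each of the 3). With 4 residual degrees of freedom and 96 families that form of the test could hardly pass, so it cannot decide. Genes with VPS symbols, named after vacuolar protein sorting but not all of that function, were higher: of 27 VPS genes 11 rose and 0 fell, with a median of 0.27 above 0 in all 5 lines (limma's camera adjusted p = 0.00621), among them VPS8 (0.57, SE 0.10), VPS33B (0.47, SE 0.10) and VPS35 (0.38, SE 0.06). Nucleoporin genes, which build the nuclear pore, were lower: of 20 NUP genes 9 fell, with a median of -0.16 (limma's camera adjusted p = 0.0232), NUP58 (-1.05, SE 0.10) and NUP88 (-0.64, SE 0.11) most, while NUP93 rose (0.47, SE 0.09). Of 20 RNA polymerase subunit genes outside the fixed lists 7 fell and 0 rose, POLR3G (-1.16, SE 0.11) and POLR2H (-0.75, SE 0.09) most, with a median of -0.13 over the lines and above 0 in 1 of the 5 (limma's camera adjusted p = 0.0206). The VPS family passed in 10 of 10 alternatives besides the estimated correlation and the others in 8, each in 1 direction.

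Lines differed in the size of the 250 nM response. Over the genes that changed in the other 4 lines, the slope of a line on their mean was 1.24 in Malme3M, 0.921 in SkMel-1, 0.885 in SkMel-19, 0.814 in SkMel-28 and 0.604 in SkMel-5. From 86.4% (SkMel-5) to 96.3% (Malme3M) of these genes had the sign of the other lines. The differences between lines were not tested.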
